A study of Arabidopsis thaliana with 12 samples.

How the data were processed

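Transcript levels of whole Arabidopsis thaliana seedlings were measured on 12 Affymetrix ATH1 arrays, 2 for each of 6 groups: the accession Col-0 and the mutants gun1-1 and abi4-102, each without and with lincomycin. Per the labels' protocols, total RNA was extracted with a column kit, labelled with biotin and hybridised by the manufacturer's procedure. The deposited table holds log2 values made by the authors with RMA, per the submitters' processing notes, a method that corrects background, equalises the distributions of the arrays and summarises the probes of a probe set. The log2 scale was read from the deposited values, whose array medians lay between 5.44 and 5.52. The version of RMA, its implementation and the probe set definition are not given in the sources used here, nor is how plastid transcripts, most of which lack a poly(A) tail, were primed. RMA makes the arrays' distributions alike, so a change in the total amount of mRNA would not be seen, and it shrinks differences between dim probe sets. The number of arrays limits the precision.

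Samples were grouped by their titles. The genotype tag of gun1-1 without lincomycin replicate 2 lists all 3 genotypes, while its title names gun1-1, and the title was used. The lincomycin concentration is 220 µg/ml in the treatment protocol and 200 µg/ml in the source name. Replicates are separate samples by their labels, but nothing states that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No replicate pair held identical values (0 of 6 pairs).

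The table held 22810 probe sets, of which 64 controls were left out and 22746 tested. In the array annotation 13513 probe sets named 1 gene, 503 named several and 8730 were unnamed here; no gene was named from a probe set with several. Of 14349 gene identifiers in the annotation, 14265 matched the gene table of assembly TAIR10.1, which served for names, gene classes and gene order only. A gene with several probe sets of its own was read from the one with the highest mean over all 12 arrays. Unnamed probe sets were brighter (mean log2 value 6.17) than named ones (5.33), so many abundant transcripts are not analysed here by name. The 2 mutated genes are among those not analysed here, so these genes give no check of the genotype labels.

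Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 12 arrays with 6 group means, which leaves 6 residual degrees of freedom. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, two-sided. The 10 comparisons were lincomycin in each genotype, the difference of that response in each mutant from Col-0, each mutant against Col-0 with and without lincomycin, and gun1-1 against abi4-102 with lincomycin. Standard errors (SE) are those of the moderated test.

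The design, 25 gene lists with 428 loci, the alternatives and the rule for named genes were fixed before the data were examined. Of the loci in these lists 106 had a probe set of their own. A probe set that names several loci counted, by the rule fixed for lists, as 1 unnamed member where all of them belong to the list, as for repeated genes of the plastid genome. This added 2 members, both in the plastid genetic system list, which gave 108 measured members, and 1 to the added plastid-encoded NDH list. Of the lists fixed first, 3 had 8 or more measured members and 4 had none. Therefore 15 more lists were added after seeing which genes the annotation names, before any fold change was computed. List shifts were tested with limma's camera at a preset correlation of 0.01, adjusted over the planned lists with at least 2 members within a comparison; for an added list the adjustment ran over all tested lists. Camera with an estimated correlation and fry were alternatives.

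The rule always named a fixed set of genes where a probe set names the gene alone, which held only for psbA and rbcL. The others, among them the mutated genes, HEMA1, GUN4, GLK1, RBCS1A and CHS, could not be read. It also named the 10 largest rises and 10 largest falls in each lincomycin comparison and each mutant against Col-0 with lincomycin. These were taken among called probe sets that name 1 gene and whose arrays separate fully between the groups. The rule named the 5 largest each way in the other comparisons. Of each list it named up to 3 called members in the prevailing direction and 1 the other way, or the 2 with the smallest p where none was called. Values of such genes are examples of a fixed rule, and the text prints part of them.

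Alternatives were the replicate number as a block, a fit of only the groups compared, an intensity trend with a robust prior, array quality weights, centring each array on its median, quantile normalization again, keeping the upper 60% of probe sets by mean, keeping probe sets that name 1 gene, an absolute log2 fold change of at least 1, and leaving out each of the 12 arrays in turn. The overlap of the mutants' differences from the same Col-0 arrays was set beside 100 simulations of unchanged groups. The procedure was tested on simulated data with 22746 probe sets made for lincomycin in Col-0. It recovered 8% of 50 probe sets changed by 0.5 on the log2 scale, 80% of 50 changed by 1, 94% of 50 changed by 2 and 100% of 50 changed by 3. It called 7 unchanged probe sets, the 1 shifted list and 0 of 19 unshifted lists. The noise was drawn independently for each probe set and the lists were random. The simulation therefore holds no correlation between genes and is no check of camera calls on the real lists.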

Results

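Whole seedlings of Arabidopsis thaliana were grown in the light for 5 days at 21 °C and 20 µmol per square metre and second on medium with 1% sucrose, without or with lincomycin, an inhibitor of translation in plastids. The series asked how the transcriptome responds to lincomycin in Col-0, in gun1-1, a mutant of a pentatricopeptide repeat protein of plastids, and in abi4-102, a mutant of a transcription factor. Each of the 6 groups held 2 arrays, and n = 2 for every group mean below. Array medians ran from 5.44 to 5.52 on the log2 scale, and replicates correlated across probe sets at r = 0.9903 to 0.9963, across genes that are not independent. The leading principal component held 42.6% of the variance. On it the Col-0 and gun1-1 arrays without lincomycin lay between 28.0 and 32.0, the abi4-102 arrays without lincomycin at 17.3 and 15.0, the Col-0 and abi4-102 arrays with lincomycin between -37.5 and -32.0, and the gun1-1 arrays with lincomycin at -8.14 and -9.85. The next component held 18.7% and set gun1-1 with lincomycin, at -35.2 and -41.3, apart from the other 10 arrays. Of these, the abi4-102 arrays without lincomycin lay at 16.1 and 19.2, and the Col-0 and gun1-1 arrays without lincomycin between -5.42 and 4.88.

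In Col-0, of the genes named by the array, AT3G28270 and AT2G27420 fell most on lincomycin, 61.8-fold (log2 fold change -5.95, SE 0.13, adjusted p = 2.94e-09) and 38.4-fold (-5.26, SE 0.16). AT3G28220 and AT1G60590 fell 17.9-fold and 17.8-fold, AT1G23205 10.1-fold, AT1G65870 8.73-fold and AT1G10640 8.71-fold, and AT5G48490 and AT1G66100 had log2 fold changes of -3.46 and -3.33. COR15A, which encodes a cold-induced chloroplast protein, fell 7.99-fold with a wider error (SE 0.61 on the log2 scale). The largest rises included 3 plastid-encoded genes: rpl16, for a ribosomal protein (6.68-fold, SE 0.21), and rpoC2 and rpoC1, for subunits of the plastid RNA polymerase (5.90-fold and 4.72-fold). MCCA, of leucine breakdown, rose with a log2 fold change of 2.58 (SE 0.19), GH3.3, which conjugates auxin, 5.11-fold and the defensin gene PDF1.4 4.90-fold. AT1G19530 rose 5.61-fold, AT1G17960 4.50-fold and AT4G21740 4.44-fold, while AT2G43620 rose 6.57-fold with an SE of 0.84 and an adjusted p of 0.0478. In all, 3948 of 22746 probe sets passed, 2139 higher and 1809 lower with lincomycin, and of the 902 that changed at least 2-fold 609 were lower. Without Col-0 without lincomycin replicate 1 or 2 the count was 2322 or 2099, of which 48.2% and 43.5% were higher, against 54.2% over all arrays. Of 2752 calls without Col-0 with lincomycin replicate 1 45.8% were higher, and of 3871 with each array centred on its median 49.99%.

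Nucleus-encoded photosynthesis transcripts fell in Col-0. All 5 measured members of the photosystem and electron transport list fell (median log2 fold change -1.41, camera adjusted p = 5.04e-09; adjusted p = 0.0615 with an estimated correlation), led by PSAE-1 of photosystem I (3.66-fold, SE 0.10) and PSBY and PSBW of photosystem II (2.77-fold and 2.66-fold). Of 3 antenna genes LHCB4.2 and LHCB4.1 fell, 2.78-fold and 2.23-fold, and 1 did not pass (list median -1.15, adjusted p = 0.062 with an estimated correlation). The 3 Calvin cycle genes SBPASE, PRK and RCA fell 3.46-fold, 2.84-fold and 1.97-fold (median -1.51, adjusted p = 0.062 with an estimated correlation). In photorespiration 3 of 4 fell, among them AT1G32470 and AT1G11860 of the glycine decarboxylase complex (3.90-fold and 2.72-fold), and the list's median was -1.35 (adjusted p = 0.062 with an estimated correlation). Adjusted over the list alone, 5 of 5 photosystem, 3 of 3 antenna, 3 of 3 Calvin cycle and 4 of 4 photorespiration genes fell. The added list of 45 nuclear photosynthesis and thylakoid genes, 11 of which are also in planned lists, had a median of -1.03. Of its members 37 fell, 0 rose and 8 did not pass, and the call held with an estimated correlation (adjusted p = 0.0438). CaS, a thylakoid protein of calcium signalling, fell 6.46-fold, NdhN of the NDH complex 5.36-fold and the thylakoid ascorbate peroxidase TAPX 4.17-fold.

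Chlorophyll and plastid translation genes fell as well. In tetrapyrrole synthesis 8 of 9 measured genes fell (8 adjusted over the list alone), among them PORB, which reduces protochlorophyllide (2.51-fold, SE 0.15), and CHLI2, a subunit of magnesium chelatase (1.98-fold). The list's median was -0.81, with a camera adjusted p of 7.93e-08 and an adjusted p = 0.062 with an estimated correlation. All 6 nuclear genes for plastid ribosomal proteins fell (6 adjusted over the list alone; median -0.75, adjusted p = 0.0754 with an estimated correlation), with AT3G13120 and AT3G54210 down 1.93-fold and 1.92-fold. The added list of plastid ribosome and translation genes, which holds those 6, had 12 of 16 down (median -0.75, adjusted p = 0.163 with an estimated correlation). The chaperonin gene Cpn60beta2 fell 3.30-fold, the lycopene cyclase gene LYC 1.43-fold and APL3, for a subunit of ADP-glucose pyrophosphorylase, 1.64-fold. AT2G21640 of the mitochondrial stress list rose 3.45-fold and the clock gene GI 1.55-fold. None of the 3 root markers, 3 epidermis and stomata markers, 4 flavonoid genes or 3 reference genes of the planned lists passed in Col-0. The planned flavonoid list had 22 loci, most of them unmeasured, and CHIL, a chalcone isomerase-like gene outside it, fell in Col-0. The root marker EXPA18 rose 2.26-fold in gun1-1, and the reference gene AT4G34270 rose 1.35-fold in gun1-1 and 1.31-fold in abi4-102, while the other 2 root markers and 2 reference genes did not pass in any genotype.

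Plastid-encoded transcripts went 2 ways in Col-0. Of 28 photosynthesis genes of the plastid genome 12 fell, 0 rose and 16 did not pass, with a median of -1.09 (camera adjusted p = 7.93e-08; adjusted p = 0.226 with an estimated correlation). psbK fell 4.05-fold, psbH 3.90-fold and psbI 3.68-fold. Adjusted over the list alone 18 fell and 2 rose. Of 23 members of the list of the plastid genetic system and other functions, 21 genes with a probe set of their own and 2 unnamed probe sets of several loci, 13 rose, 1 fell and 9 did not pass, with a median of 1.15 (adjusted p = 0.24 with an estimated correlation; 13 rose and 2 fell adjusted over the list alone). Among those that rose were rpl16, rpoC2 and rpoC1. The exception was rpl33, which fell 3.36-fold. psbA and rbcL did not pass (log2 fold changes -1.25, SE 0.42, and -0.49, SE 0.23).

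In gun1-1 lincomycin raised AT1G18830 11.4-fold (SE 0.17, adjusted p = 3.42e-06), AT4G21740 10.4-fold, AT1G43910 9.40-fold and the beta-glucosidase gene BGLU25 9.11-fold. AT5G17760 rose 7.37-fold, AT4G25580 5.67-fold, AT5G13880 5.46-fold, AT2G21640 5.30-fold, COR27 5.19-fold and AT5G37670 5.13-fold. Of the 10 largest falls 6 were plastid-encoded: psbH (6.47-fold, SE 0.21), psbE (5.73-fold), psaJ (5.72-fold, SE 0.12), psbJ (5.58-fold), ndhC (5.52-fold) and petB (5.15-fold). The other falls were AT1G66100 (12.2-fold, SE 0.45), AT3G33066 (6.48-fold), AT1G23205 (5.99-fold) and AT1G10640 (5.12-fold). In all 2432 probe sets passed, 1317 higher and 1115 lower, while of the 435 that changed at least 2-fold 197 were higher and 238 lower. The count was 1145 or 1241 without gun1-1 without lincomycin replicate 1 or 2, 1149 without gun1-1 with lincomycin replicate 2, and 766 in a fit of the gun1-1 arrays alone.

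Of the 45 nuclear photosynthesis and thylakoid genes 9 fell in gun1-1, 2 rose and 34 did not pass (median -0.26, adjusted p = 0.62 with an estimated correlation). TAPX fell 2.04-fold and CaS 1.83-fold, and AT5G64380 rose 1.61-fold. PSAE-1 alone of 5 photosystem genes fell, 1.39-fold (list median -0.32, adjusted p = 0.25 with an estimated correlation), and in the antenna list LHCB4.3 and LHCB4.2 fell 1.56-fold and 1.33-fold (median -0.41, adjusted p = 0.25 with an estimated correlation). None of 3 Calvin cycle, 4 photorespiration or 6 plastid ribosomal protein genes passed. Adjusted over the list alone, 4 photosystem, 2 antenna, 2 Calvin cycle, 0 photorespiration and 0 plastid ribosomal protein genes fell. In tetrapyrrole synthesis PORB fell 2.95-fold, HEME1, a uroporphyrinogen decarboxylase gene, rose 1.44-fold and 7 did not pass (median -0.03). The plastid-encoded photosynthesis genes had 14 of 28 down, 0 up and a median of -1.11 (18 down adjusted over the list alone; adjusted p = 0.25 with an estimated correlation). In the plastid genetic system list 8 rose, 2 fell and 13 did not pass (9 and 2 adjusted over the list alone; median 0.48, adjusted p = 0.532 with an estimated correlation), with rpoC2 up 4.52-fold, rpoC1 3.34-fold, rps2 2.65-fold and rpl33 down 4.84-fold. In the mitochondrial stress list AT2G21640 and AT5G09570 (1.75-fold) of 3 rose (median 0.81, adjusted p = 0.25 with an estimated correlation).

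In abi4-102 the largest falls on lincomycin were in AT2G27420 and AT3G28270, with log2 fold changes of -4.64 each (SE 0.16 and 0.13), followed by AT1G60590 (10.5-fold), AT2G25510 (8.29-fold, SE 0.45), AT3G28220 (7.49-fold), AT5G48490 (6.64-fold), AT1G65870 (6.41-fold), AT1G62290 (5.61-fold), AT1G21500 (5.39-fold) and AT1G23205 (5.11-fold). Plastid-encoded genes made up 5 of the 10 largest rises: rpl14 (9.16-fold, SE 0.23), rpl36 (8.34-fold), rpl16 (7.13-fold), rpl20 (6.60-fold) and rpoC2 (6.13-fold). AT1G17960 rose 10.9-fold, AT2G04050 7.74-fold, AT2G21640 5.83-fold, AT4G21740 5.34-fold and AT4G25580 5.21-fold. In all 2993 probe sets passed, 1739 higher and 1254 lower, while of the 503 that changed at least 2-fold 194 were higher and 309 lower. The count was 1489 or 1156 without abi4-102 without lincomycin replicate 1 or 2, of which 55.9% and 47.1% were higher against 58.1%, 1692 without abi4-102 with lincomycin replicate 1, 2052 without its replicate 2, of which 49.6% were higher, and 1966 in a fit of the abi4-102 arrays alone.

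Of the 45 nuclear photosynthesis and thylakoid genes 32 fell in abi4-102, 0 rose and 13 did not pass (median -0.65, adjusted p = 0.0807 with an estimated correlation), with CaS down 3.61-fold, NdhN 3.48-fold and PSAE-1 2.86-fold. All 5 photosystem genes (median -0.88), all 3 antenna genes (-0.79) and all 3 Calvin cycle genes (-0.92) fell, as did 3 of 4 photorespiration genes (-0.85). The camera calls of these lists were lost with an estimated correlation (adjusted p = 0.0807, 0.083, 0.119 and 0.125). In tetrapyrrole synthesis 4 of 9 fell (7 adjusted over the list alone; median -0.44, adjusted p = 0.125 with an estimated correlation), with PORB down 2.73-fold and HEMB1 1.64-fold. Of 6 plastid ribosomal protein genes 1 fell (3 adjusted over the list alone; median -0.40, adjusted p = 0.233 with an estimated correlation). Of the plastid-encoded photosynthesis genes 11 fell, among them psbC (4.26-fold), 3 rose, led by psaI (2.70-fold), and 14 did not pass. Their median was -0.25 (adjusted p = 0.518 with an estimated correlation), and 12 fell and 4 rose adjusted over the list alone. In the plastid genetic system list 16 of 23 rose and rpl33 fell 4.22-fold (median 1.42, adjusted p = 0.125 with an estimated correlation; 19 rose and 2 fell adjusted over the list alone).

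**Figure D1:**
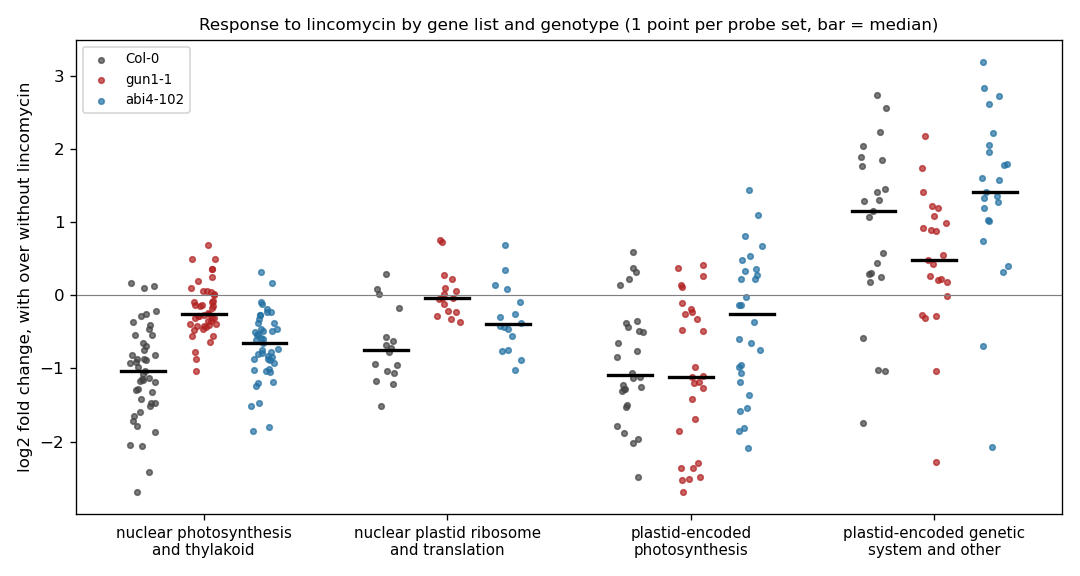
Log2 fold change with over without lincomycin (vertical axis) for each measured member of 4 lists (horizontal axis) in Col-0, gun1-1 and abi4-102; each point is 1 probe set, from group means of 2 arrays, and bars are list medians. The nuclear photosynthesis and thylakoid list has medians of -1.03, -0.26 and -0.65 in the 3 genotypes, and the plastid-encoded photosynthesis list -1.09, -1.11 and -0.25.

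The difference of the lincomycin response between gun1-1 and Col-0 was tested directly. Responses are signed log2 fold changes, so a higher response can be a smaller fall and a lower one a larger fall. AT3G28270 and AT2G27420, which fell less in gun1-1, differed most. Their ratios of with to without lincomycin were 23.6-fold and 15.3-fold higher in gun1-1 (log2 differences 4.56, SE 0.19, and 3.94, SE 0.22). AT5G42760 (9.15-fold), AT1G65870 (7.24-fold) and AT1G73600 (6.62-fold) followed. Responses lower in gun1-1 were led by AT1G12080 (5.58-fold), rpl16 (3.63-fold), GH9B13 (3.60-fold), AT5G44400 (3.35-fold) and AT1G80280 (3.31-fold). In all 997 probe sets passed, 733 with a higher and 264 with a lower response in gun1-1. The count was 424 or 392 without Col-0 without lincomycin replicate 1 or 2, with 80.2% and 87.0% higher against 73.5% over all arrays, and 529 without gun1-1 without lincomycin replicate 1.

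Of the 45 nuclear photosynthesis and thylakoid genes 27 had a higher response in gun1-1 than in Col-0, 0 a lower one and 18 did not pass. The median difference was 0.89, and the list's call held with an estimated correlation (adjusted p = 0.0427). NdhL differed by 1.92 (SE 0.22), NdhN by 1.87 and CaS by 1.82. The responses of all 5 photosystem genes (median 1.12), all 3 Calvin cycle genes (1.19), 3 of 4 photorespiration genes (1.16), 2 of 3 antenna genes (0.88) and 5 of 9 tetrapyrrole genes (0.78), among them HEME1 and CHLI2, were higher. With an estimated correlation these calls were lost (adjusted p = 0.0572, 0.0651, 0.0651, 0.179 and 0.0651), and adjusted over the list alone the counts were 5, 3, 3, 2 and 6. Of 6 plastid ribosomal protein genes 1 passed and 6 did adjusted over the list alone (median 0.72, adjusted p = 0.101 with an estimated correlation). Of 28 plastid-encoded photosynthesis genes 4 had a lower response in gun1-1, led by psaJ (log2 difference -1.39, SE 0.17) and psbM (-1.34), 0 a higher one and 24 did not pass, while 11 were lower adjusted over the list alone. The list was split, with 16 differences below 0 and 12 above; petD (1.65, SE 0.75, adjusted p = 0.303) and psbB (1.5, SE 1.13, adjusted p = 0.584), named after their values were seen, had the largest positive ones and did not pass. The list's median was -0.23, and its call was lost with an estimated correlation (adjusted p = 0.584). In the genetic system list rpl16 and rpl22 had a lower response (5 genes adjusted over the list alone; median -0.38, adjusted p = 0.492 with an estimated correlation).

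No probe set passed for a difference in lincomycin response between abi4-102 and Col-0 in the limma fit: the count was 0, with 2230 probe sets at an unadjusted p under 0.05. It was 9 with an intensity trend and a robust prior, 1 without Col-0 without lincomycin replicate 1 and 4 without Col-0 with lincomycin replicate 1. By camera, nuclear lists shifted upwards, with medians of 0.41 for photosynthesis and thylakoid (adjusted p = 0.273 with an estimated correlation) and 0.33 for tetrapyrrole synthesis (adjusted p = 0.335 with an estimated correlation). The plastid-encoded photosynthesis list had a median of 0.40 (adjusted p = 0.48 with an estimated correlation). The members with the smallest p did not pass: LHCB4.2 differed by 0.86 (SE 0.16, adjusted p = 0.149) and NdhL by 1.27 (SE 0.22, adjusted p = 0.148). Adjusted over the list alone, 2 of 5 photosystem, 2 of 3 Calvin cycle, 2 of 4 photorespiration and 3 of 6 plastid ribosomal protein genes had a higher response in abi4-102, and of 3 antenna genes 1 had a higher and 1 a lower one. The photosynthesis and thylakoid list differed between abi4-102 and Col-0 by a median of -0.21 without lincomycin and 0.10 with it. The difference without lincomycin was the larger in size, but neither difference was called with an estimated correlation. The medians were not tested against each other.

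With lincomycin, AT3G28270 was 16.5-fold higher in gun1-1 than in Col-0 (log2 fold change 4.04, SE 0.13, adjusted p = 1.82e-07) and AT2G27420 13.6-fold. AT1G65870 was 8.80-fold, AT5G42760 7.58-fold, AT1G21500 6.31-fold, AT3G48420 5.90-fold, AT1G73600 5.64-fold, AT4G37560 5.43-fold, AT5G37670 5.22-fold and AT1G60590 5.14-fold higher. OSM34, an osmotin gene, was 9.70-fold lower (SE 0.64 on the log2 scale), AT1G30700 4.37-fold, rpl16 3.72-fold, AT1G72060 3.65-fold, AT1G67865 3.60-fold, the cytochrome P450 gene CYP71B23 3.44-fold and AT3G44970 3.18-fold. AT1G52000, AT1G12080 and PDF1.4 were 3.12-fold, 3.04-fold and 2.97-fold lower. In all 2279 probe sets passed, 1361 higher and 918 lower in gun1-1, and of the 544 that differed at least 2-fold 406 were higher. The count was 1501, with 72.2% higher, without gun1-1 with lincomycin replicate 2, against 59.7% over all arrays, and 1080 in a fit of the 4 arrays alone.

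Of the 45 nuclear photosynthesis and thylakoid genes 36 were higher in gun1-1 with lincomycin, 0 lower and 9 did not pass (median 0.89, adjusted p = 0.035 with an estimated correlation, so the call held). NdhN was 3.85-fold, NdhL 3.47-fold, CaS 3.32-fold and PSAE-1 2.78-fold higher. All 5 photosystem, 3 Calvin cycle and 6 plastid ribosomal protein genes, 7 of 9 tetrapyrrole genes (9 adjusted over the list alone) and 2 of 3 antenna genes were higher. HEME1 was 2.69-fold and SBPASE 2.72-fold higher, and Cpn60beta2 3.17-fold. With an estimated correlation the planned nuclear lists were not called (adjusted p = 0.0529 for photosystem and for tetrapyrrole genes, and 0.0664 for the others). Of the plastid-encoded photosynthesis genes 13 of 28 were lower and 0 higher (15 lower and 1 higher adjusted over the list alone; median -0.62, adjusted p = 0.234 with an estimated correlation), among them psbJ (2.68-fold), psaJ (2.48-fold) and psbC (2.39-fold). In the genetic system list 8 of 23 were lower (13 adjusted over the list alone; median -0.76, adjusted p = 0.178 with an estimated correlation), with rpl22 2.56-fold and rpoA 2.21-fold lower.

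Between abi4-102 and Col-0 with lincomycin, QQS, which affects starch content, was 13.8-fold higher in abi4-102 (log2 fold change 3.78, SE 0.12, adjusted p = 1.73e-07). AT5G03090 and AT2G15560 were 9.07-fold and 8.43-fold higher, AT5G44440 6.12-fold (SE 0.47, adjusted p = 0.0435), AT4G03530 4.48-fold, AT2G13160 3.89-fold, AT5G43800 3.81-fold, AT5G26020 3.62-fold, and AT3G43640 and AT2G20460 3.58-fold each. Lower in abi4-102 were AT2G25510 (5.49-fold, SE 0.45, adjusted p = 0.0497), the defensin-like gene LCR68 (4.58-fold), ECS1 (3.86-fold), AT5G50310 (3.72-fold), AT1G18810 (2.85-fold), the thionin gene THI2.2 (2.74-fold), AT4G16870 (2.31-fold), AT3G44970 (2.13-fold) and AT3G54510 (2.00-fold). Only 104 probe sets passed, 71 higher and 33 lower. The count was 55 or 65 without abi4-102 with lincomycin replicate 1 or 2, 66 or 46 without Col-0 with lincomycin replicate 1 or 2, 46 without either Col-0 array without lincomycin, and 21 in a fit of the 4 arrays alone. LHCB4.2, of 45 nuclear photosynthesis and thylakoid genes, was higher, 1.53-fold, and the other 44 did not pass (median 0.10, adjusted p = 0.583 with an estimated correlation). PORB was 1.77-fold, APL3 1.74-fold and the plastid-encoded psaJ 1.74-fold higher. By camera the plastid-encoded photosynthesis and genetic system lists were higher (medians 0.36 and 0.45; adjusted p = 0.376 with an estimated correlation for both).

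Without lincomycin, gun1-1 and Col-0 differed in 5 probe sets, 3 higher and 2 lower in gun1-1, with 1532 at an unadjusted p under 0.05. The 3 that name a gene were AT3G55920 (3.18-fold higher, SE 0.13), AT3G05170 (2.16-fold higher) and AT3G44970 (2.74-fold lower). The count was 24 without gun1-1 without lincomycin replicate 2, the array with the odd genotype tag, and 0 without Col-0 without lincomycin replicate 2. It was 1 without Col-0 without lincomycin replicate 1, either abi4-102 array without lincomycin or either gun1-1 array with lincomycin, and 2 without either Col-0 array with lincomycin. None of the 45 nuclear photosynthesis and thylakoid genes passed (median 0.01). By camera the plastid-encoded photosynthesis list was lower in gun1-1 (median -0.26, adjusted p = 0.984 with an estimated correlation), with 0 of 28 members called, over all probe sets or adjusted over the list alone. The genetic system list was lower likewise (median -0.29, adjusted p = 0.984 with an estimated correlation), and its call was lost without gun1-1 without lincomycin replicate 1 (adjusted p = 0.95) or Col-0 without lincomycin replicate 2 (adjusted p = 0.906).

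Without lincomycin, abi4-102 had QQS 10.4-fold (SE 0.12), AT5G44440 7.12-fold, AT2G15560 6.91-fold, AT5G03090 5.86-fold and AT2G20460 4.06-fold higher than Col-0. AT3G44970 was 4.15-fold, AT5G50310 3.38-fold, THI2.2 3.27-fold, AT3G58550 3.10-fold and FACT, for an acyltransferase, 2.98-fold lower. In all 383 probe sets passed, 208 higher and 175 lower, 121 of them at least 2-fold. The count was 189 or 49 without abi4-102 without lincomycin replicate 1 or 2, 58 or 39 without Col-0 without lincomycin replicate 1 or 2, 761 in a fit of the 4 arrays alone and 1602 with array quality weights, of which 47.2% were higher against 54.3%. PORB was 1.92-fold higher, and 8 of 9 tetrapyrrole genes did not pass. Of the 45 nuclear photosynthesis and thylakoid genes 0 passed over all probe sets and 12 were lower adjusted over the list alone (median -0.21, adjusted p = 0.588 with an estimated correlation).

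Between gun1-1 and abi4-102 with lincomycin 2478 probe sets passed, 1370 higher and 1108 lower in gun1-1. AT3G28270 was 16.9-fold (SE 0.13), AT5G42760 14.4-fold, AT2G27420 13.2-fold, AT2G25510 9.61-fold and AT1G65870 8.31-fold higher in gun1-1. QQS was 15.5-fold, AT2G15560 9.42-fold, OSM34 8.55-fold, AT5G03090 6.90-fold and AT1G26250 6.82-fold lower. Of the 45 nuclear photosynthesis and thylakoid genes 39 were higher in gun1-1 and 0 lower (median 0.79, and the call held at adjusted p = 0.0486 with an estimated correlation). All 5 photosystem, 3 antenna and 3 Calvin cycle genes, 3 of 4 photorespiration and 5 of 9 tetrapyrrole genes were higher, and these calls were lost with an estimated correlation (adjusted p = 0.0861 for each). Of the plastid-encoded photosynthesis genes 16 of 28 were lower, with psaI 4.70-fold and psaJ 4.31-fold (median -1.07, adjusted p = 0.102 with an estimated correlation; 19 adjusted over the list alone). In the genetic system list 17 of 23 were lower, with rpl16 5.85-fold and rpl14 4.86-fold (median -1.21, adjusted p = 0.0883 with an estimated correlation; 20 adjusted over the list alone). The count was 1450 without abi4-102 with lincomycin replicate 1, 1538 with 65.7% higher without gun1-1 with lincomycin replicate 2, 1311 in a fit of the 4 arrays alone and 1531 with array quality weights. With each array centred on its median 65.6% of 2424 calls were higher, against 55.3%.

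**Figure D2:**
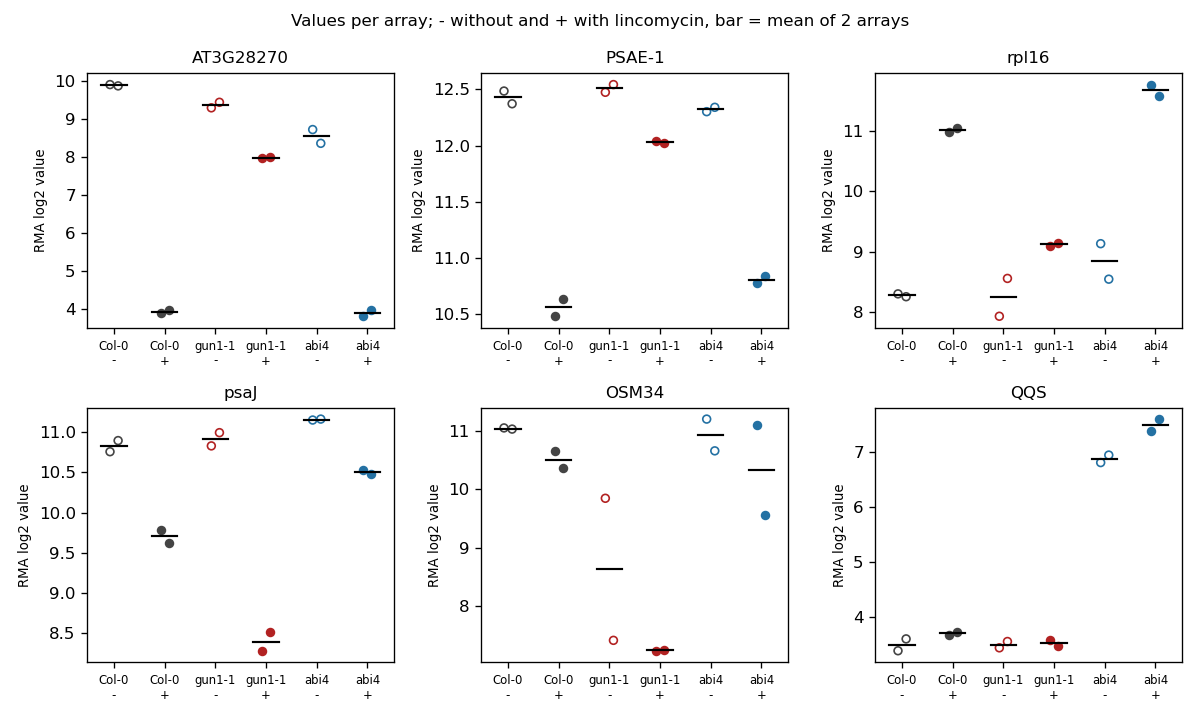
RMA log2 value (vertical axis) of 6 genes on each of the 12 arrays, by genotype without (open) and with (filled) lincomycin; bars are means of 2 arrays. AT3G28270 and PSAE-1 stay higher in gun1-1 than in Col-0 with lincomycin (16.5-fold and 2.78-fold), and QQS is higher in abi4-102 on both media (10.4-fold and 13.8-fold).

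The differences of gun1-1 and abi4-102 from Col-0 with lincomycin shared 25 probe sets in the same direction, 18 higher and 7 lower in both mutants, and 4 passed in opposite directions. Among them LHCB4.2 was higher in both (2.14-fold and 1.53-fold), as were AT5G38510 (log2 fold changes 1.63 and 0.70) and AT3G05170 (1.35 and 1.68). AT3G44970 was lower in both (-1.67 and -1.09), and psaJ was lower in gun1-1 and higher in abi4-102 (-1.31 and 0.80). Of the shared genes, AT3G55920, AT3G05170 and AT3G44970 differed between gun1-1 and Col-0 in the same directions without lincomycin. AT3G44970 was also lower in abi4-102 without lincomycin. The differences of these genes are thus not particular to seedlings with lincomycin. AT5G38510 was chosen here after its values were seen. Both comparisons use the same 2 Col-0 arrays. In 100 simulations of unchanged groups the shared count was 0 at the median and 0 at the highest, but unchanged groups give few calls, so this is no measure of the overlap that shared controls add beside real effects. Independent lists of these sizes, which leave out the shared arrays, would share 4.25 higher and 1.33 lower. The covariance of the log2 fold changes was 0.0256, against 0.0158 to 0.0192 in the simulations, and their correlation across probe sets, which are not independent, was 0.275, below the 0.462 to 0.527 of the simulations. Part of the excess over independent lists may come from the shared controls, which are too few to split, and the overlap was not tested beyond these values. The overlap was 6 without either Col-0 array without lincomycin, 7 without Col-0 with lincomycin replicate 2, and 12 or 14 without abi4-102 with lincomycin replicate 1 or 2.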

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

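The test of scaling between arrays was chosen after the result was seen; the other tests of this part were chosen before. Each value here is a difference of the lincomycin response between a mutant and Col-0, found by the test of that difference.

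In gun1-1 against Col-0 997 probe sets differed in response. The called genes given here were named for the largest changes on lincomycin in Col-0 or gun1-1, or in this difference. Genes named only as list members, among them NdhL, NdhN, CaS and GSTU18, are given elsewhere. The log2 differences were 4.56 for AT3G28270, 3.94 for AT2G27420, 3.19 for AT5G42760 and 2.85 for AT1G65870. Differences of 2.73 for AT1G73600, 2.44 for AT1G60590 and 2.33 for AT5G37670 followed. They were 2.06 for AT3G28220, 1.97 for AT1G43910, 1.88 for AT1G18830, 1.80 for AT5G48490, 1.61 for BGLU25 and 1.56 for AT5G13880. Below 0 lay petB (-1.24), psaJ (-1.39), AT1G19530 (-1.47), AT1G80280 (-1.73), AT5G44400 (-1.75), GH9B13 (-1.85), rpl16 (-1.86) and AT1G12080 (-2.48).

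By camera 14 lists differed between gun1-1 and Col-0. Their median differences were 0.88 for the antenna, 1.12 for photosystem and electron transport, 1.19 for the Calvin cycle, 1.16 for photorespiration, 0.78 for tetrapyrrole synthesis and 0.72 both for nuclear plastid ribosomal proteins and for plastid ribosome and translation. They were 0.89 for nuclear photosynthesis and thylakoid, 0.51 for plastid RNA editing, 0.14 for endoplasmic reticulum stress (0.145), -0.23 for plastid-encoded photosynthesis, -0.38 for the plastid genetic system, -0.27 for expansins and -0.24 for cell division (-0.245). With an estimated correlation only nuclear photosynthesis and thylakoid was called (adjusted p = 0.0427), and the highest adjusted p of the others was 0.609.

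For abi4-102 against Col-0 11 lists differed by camera, with 0 probe sets called. The median differences were 0.35 for photosystem and electron transport, 0.60 for the Calvin cycle, 0.46 for photorespiration, 0.33 for tetrapyrrole synthesis, 0.43 for nuclear plastid ribosomal proteins and 0.40 for plastid-encoded photosynthesis. They were 0.27 for the plastid genetic system, 0.41 both for nuclear photosynthesis and thylakoid (0.406) and for plastid ribosome and translation (0.413), 0.67 for the plastid NDH complex and 0.28 for plastid RNA editing (0.285). None was called with an estimated correlation, where the lowest adjusted p was 0.273. For nuclear photosynthesis and thylakoid, abi4-102 lay below Col-0 without lincomycin by a larger median than it lay above Col-0 with it. Neither difference in level was called with an estimated correlation, and the medians were not tested against each other.

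Nuclear photosynthesis transcripts fell less on lincomycin in gun1-1 than in Col-0. A weaker lincomycin effect in the gun1-1 seedlings was taken to shrink rises and falls alike, which was not tested. Probe sets not annotated to the plastid genome, unnamed ones included, were chosen by their response on the abi4-102 arrays. The median gun1-1 response was 0.815 of that in Col-0 for the 1711 that rose there. It was 0.413 for the 1241 that fell (0.74 to 0.879 against 0.383 to 0.458 with 1 array left out). Those that fell include photosynthesis genes of the pattern itself, so the lower ratio partly restates it. The unequal ratios argue against such a uniform weakening as the whole cause. They cannot decide about a weaker effect that shrinks falls more than rises. A scaling difference left in the deposited values would move all probe sets, whose median difference was -0.0387. RMA makes the arrays' distributions alike, which holds this median near 0, so it cannot decide about scaling before RMA. The shift did not rest on the array with the odd tag: it was 0.924 without that array, and 0.89 between gun1-1 and Col-0 with lincomycin, whose group means leave that array out, which does not settle the genotype of the array itself. The gun1-1 mutation itself stays among the open explanations, as untested, since with 1 line per mutant it cannot be separated from other differences between the lines, their seed lots or their growth.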

How the results depend on the processing

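No test in this part was chosen after the data were seen. Of 815 results on single named genes, 742 to 770 kept their side of the threshold when 1 array was left out. The lowest was without Col-0 without lincomycin replicate 2. Under the other settings that ran all 815, 731 to 807 kept it, the lowest in the fit of only the groups compared. The filter on dim probe sets ran 712 of them, of which 706 did so. Of 300 list results 279 to 294 did so when 1 array was left out, and 206 with an estimated correlation. Direction was compared only where a result was called in either fit, so results called in neither may have changed sign. No single gene turned direction past the threshold. An array left out leaves a lone array that is assumed to vary like the other groups, and dim probe sets have signal near background, which limits small changes.

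The direction of camera's test turned for 3 lists where the list was called in either fit. Cold and dehydration proteins in abi4-102 against Col-0 with lincomycin were not called over all arrays (median 0.0004, adjusted p = 0.879), and were called at a median of -0.269 without Col-0 with lincomycin replicate 2 and of 0.206 without its replicate 1. Plastid ribosome and translation in gun1-1 against Col-0 without lincomycin was not called over all arrays either (median 0.006, adjusted p = 0.977), and was called at 0.119 without gun1-1 without lincomycin replicate 1 and at -0.0965 without its replicate 2. The plastid genetic system, called in that comparison at -0.287, was not called at -0.256 without gun1-1 without lincomycin replicate 1, where the test's direction turned and the median's did not (medians -0.515 to -0.0575 with 1 array left out). The cause was not tested.

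Called probe sets with 1 array left out ran from 2099 to 4059 for lincomycin in Col-0, 1145 to 2485 in gun1-1 and 1156 to 3091 in abi4-102. They ran from 392 to 971 for the response difference of gun1-1 and 0 to 4 for that of abi4-102. For gun1-1 against Col-0 they ran from 1501 to 2283 with and 0 to 24 without lincomycin, for abi4-102 against Col-0 from 46 to 96 with and 39 to 409 without, for gun1-1 against abi4-102 from 1450 to 2512, and for the overlap from 6 to 27. Fewer arrays leave fewer degrees of freedom, also where the array left out is in neither group compared.

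Fits of only the groups compared called 766 for lincomycin in gun1-1 and 1966 in abi4-102, 1080 for gun1-1 and 21 for abi4-102 against Col-0 with lincomycin, 761 for abi4-102 against Col-0 without (383 in the fit of all arrays) and 1311 for gun1-1 against abi4-102; the cause was not tested. Array quality weights, which favour the Col-0 and abi4-102 arrays without lincomycin (weights 1.69 and 1.41, against 0.688 for gun1-1 with lincomycin), gave 1587 for lincomycin in gun1-1, 67 and 1602 for abi4-102 against Col-0 with and without lincomycin, and 1531 for gun1-1 against abi4-102, and the cause was not tested. An intensity trend with a robust prior gave 9 for the response difference of abi4-102, and the cause was not tested. The filter on dim probe sets gave 62 for abi4-102 against Col-0 with lincomycin and 1 for gun1-1 without, and quantile normalization again 2 for the latter, both higher; the cause was not tested.

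Only probe sets that name 1 gene, which are fewer, gave 1960, 1252 and 1588 for lincomycin in Col-0, gun1-1 and abi4-102, 466 for the response difference of gun1-1, 1104 and 3 for gun1-1 against Col-0 with and without lincomycin, 65 and 134 for abi4-102, and 1295 for gun1-1 against abi4-102. An absolute log2 fold change of at least 1, a stricter bound, left 902, 435 and 503 for lincomycin, 540 for the response difference of gun1-1, 544 and 54 for gun1-1 and abi4-102 against Col-0 with lincomycin, 121 for abi4-102 without, 559 for gun1-1 against abi4-102 and 6 of the overlap. Of 59 camera calls of planned lists 0 held with an estimated correlation (lowest adjusted p 0.0529), and of 39 calls of added lists 4 did; fry called 48 planned list shifts by direction and 42 in either direction.

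With the replicate number as a block the counts were 3881, 2297 and 2844 for lincomycin in Col-0, gun1-1 and abi4-102, 903 and 0 for the response differences, 2209 and 4 for gun1-1 against Col-0 with and without lincomycin, 91 and 358 for abi4-102, 2338 for gun1-1 against abi4-102, 23 for the overlap and 58 list calls, all within 1.5 times. The numbers did not pair the samples consistently: deviations of same-numbered arrays correlated between -0.283 and 0.281, over 0.1 in 3 of 15 pairs of groups. A batch shared by some groups under other numbers is not excluded by this check.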

Other observations

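The tests of pseudogenes, of shared sign and of neighbouring plastid genes were chosen after their results were seen at least in part; the test of neighbouring nuclear genes was chosen before.

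In gene groups outside the plastid some members changed on lincomycin. Of 9 ATG8 genes, which encode autophagy proteins, 4 rose in Col-0 (median 0.37, adjusted p = 0.286 with an estimated correlation), led by ATG8F (1.69-fold, SE 0.10), and 2 rose in gun1-1 and 3 in abi4-102 (adjusted p = 0.62 and 0.374 with an estimated correlation). In the endoplasmic reticulum stress list 4 of 14 rose in Col-0 and 5 in gun1-1. BZIP60, a transcription factor of the unfolded protein response, rose 1.65-fold in Col-0 and 2.50-fold in gun1-1, and OS9 2.49-fold in gun1-1, while Fes1A, a cofactor of Hsp70, fell 3.16-fold and 2.52-fold. The list's call in gun1-1 was lost with an estimated correlation (adjusted p = 0.117). In Col-0 it was not called (adjusted p = 0.118). Of 18 expansins, which loosen cell walls, 3 fell in Col-0, where the list was not called (adjusted p = 0.274), and 7 in gun1-1, where EXPB1 fell 4.27-fold (SE 0.17), EXPB3 3.70-fold and EXPA16 2.95-fold and EXPA18 rose 2.26-fold (median -0.36, adjusted p = 0.117 with an estimated correlation).

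GSTU18, 1 of 11 tau-class glutathione transferase genes, fell 3.76-fold in Col-0 and differed in response by 2.00 (SE 0.18) in gun1-1, where it did not pass. In abi4-102 2 of the 11 fell, and the list's call was lost with an estimated correlation (adjusted p = 0.207). AGL87, 1 of 40 MADS-box genes, fell 3.09-fold in Col-0 and 2.40-fold in abi4-102, CHIL, a chalcone isomerase-like gene, 3.51-fold, 2.35-fold and 2.31-fold in Col-0, gun1-1 and abi4-102, and the kinase gene AUR2 2.59-fold, 1.66-fold and 2.76-fold. XTH32 of the xyloglucan hydrolases fell 2.63-fold in Col-0. Of 10 genes for plastid RNA editing 2 fell in Col-0, among them CRR21 2.15-fold, and the list's call was lost with an estimated correlation (camera adjusted p = 0.0119; adjusted p = 0.113 with an estimated correlation). With lincomycin 4 of the 10 were higher in gun1-1 than in Col-0 (adjusted p = 0.0818 with an estimated correlation). The plastid-encoded NDH list held 10 genes and 1 unnamed probe set of several loci. In Col-0 1 of these 11 rose and 2 fell, and in gun1-1 1 rose and 4 fell, where the call was lost with an estimated correlation (camera adjusted p = 0.0455; adjusted p = 0.676 with an estimated correlation). Among them ndhH rose 2.36-fold and 1.69-fold and ndhC fell, with log2 fold changes of -1.14 and -2.46, in Col-0 and gun1-1. With lincomycin 4 of the 11 were lower in gun1-1 than in Col-0 and 7 than in abi4-102 (adjusted p = 0.233 and 0.153 with an estimated correlation). In Col-0 2 of 47 UDP-glycosyltransferase genes rose and 4 fell, and 0 of 7 ER body and jacalin lectin genes passed.

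abi4-102 and Col-0 differed in the same direction on both media, in comparisons that share no array: 52 probe sets passed in both, all 52 in the same direction, and of the 383 that passed without lincomycin 82.0% had the same sign with it (94.2% of the 121 that differed at least 2-fold), which argues against chance calls. Of 32 named genes that passed in both, 3 pairs lay within 5 named genes of each other, against 0.373 in random draws (permutation p = 0.00687, one-sided). The pairs were LCR69 and LCR68, which are related genes, AT2G15510 and AT2G15560, and AT5G50310 and AT5G50335. The AT2G15510 and AT5G50310 pairs lie on different chromosomes, so a single stretch that differs between the lines could not account for all 3 pairs. Stretches at separate places could account for a few of the genes. Pseudogenes, the class in which the gene table holds transposon-like loci, made up 28.1% (9 of 32) against 7.44% of all named genes (one-sided Fisher's exact test, p = 0.000397), and all 9 were higher in abi4-102, which is consistent with a heritable difference at such loci. The effect of the mutation itself was not tested apart from the line that carries it.

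The plastid-encoded photosynthesis and genetic system lists had medians of -1.09 and 1.15 on lincomycin in Col-0, with both camera calls lost with an estimated correlation (adjusted p = 0.226 and 0.24) and no test of one list against the other, and neighbours on the plastid genome may respond together. Within lists, the Col-0 response correlated at r = 0.206 between neighbours over 49 genes in order, which are not independent, against a 95th percentile of 0.219 in permutations (permutation p = 0.061, one-sided). The bound written first counted any p of 0.05 or more against this explanation; it was replaced after the value was seen, since a p just over the threshold does not show that neighbours respond independently. The bounds of the tests of neighbouring nuclear genes and of pseudogenes were changed alike, which left their outcomes as they were. The explanation therefore cannot be told apart from independent responses with these 49 genes.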
